A study of Drosophila melanogaster with 4 samples.

How the data were processed

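ChIP-seq was done on cross-linked chromatin of whole embryos of the Oregon-R strain, with rat antibodies to ZAF1 (2 libraries) and dCTCF (1 library) and with preimmune rat IgG (1 library), per the labels. Groups, and the replicate numbers of the ZAF1 libraries, were taken from the sample labels. The labels describe the libraries as sequenced in single-end mode. Reads passed through cutadapt, Bowtie and Picard in roles that are not given, and peaks were called with MACS2, per the submitters' processing notes, and versions and thresholds are not given in the sources used here. The notes name builds dm6 and dm3, and the peaks reach past the arm lengths of dm3, so coordinates are read as dm6 and are printed counting from 1.

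The authors deposited 2 peak lists, each called against the preimmune library, and no read counts, so depth per library is unknown. The deposited fold enrichment of a peak is a ratio over the control as the peak caller writes it, and it was used here to describe and rank peaks within a list. The deposited −log10 p and −log10 q of each peak are the caller's values, and peaks were ranked by −log10 q. The deposited score of a dCTCF peak equalled 10 times its −log10 p, rounded down, in all 712 peaks, and the score of a ZAF1 peak followed from the global irreproducible discovery rate in all 92. The ZAF1 list is named as merged, and whether reads or peaks were merged is not stated. It has the 20 columns of an irreproducible discovery rate table, with the deposited −log10 p of the same peak in 2 replicate calls. The layout does not say which replicate is which, or whether the calls came from the 2 libraries or from splits of the reads. The calls gave identical values in 4 of 92 peaks, and the merged −log10 p lay below both in 65 of 92, so the values of replicate and merged calls were not set side by side. The global rate reached at most 0.00409, and 2 ZAF1 peaks had a q above 0.05. The dCTCF list was called on its 1 library, without a replicate.

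Genes came from a table of RefSeq genes for Release 6 of the genome, the same build, with 17872 genes, of which 13922 are protein-coding genes on the 6 arms used (2L, 2R, 3L, 3R, 4 and X). It gives gene spans without strand or exons. No genome sequence was used here. The planned tests of the CTCF core in peaks and of leading short sequence words, and placements matched on base composition, were therefore not run, which left 6 planned results out. Divergent start pairs and exon, intron and UTR classes were replaced by gene ends, gaps between protein-coding genes, and spans. A gap is a stretch covered by no protein-coding gene. A peak was placed by its summit.

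Random placements moved each peak to a uniform position between the first and last gene of its arm, keeping its width and summit offset, 10000 times, and a two-sided permutation p is 2 times the smaller tail with the observed value counted in. The smallest such p is 0.0002. Gene-end-matched placements kept each summit's distance from a gene end and its side of that end, at a random gene of the arm. Overlap meant at least 1 bp in common. Proportions were compared by two-sided Fisher's exact tests, medians by permutation with 100000 resamples, and shares have Wilson 95% intervals. Gene lists, 13 in all with 452 members, were written before the data were examined, together with the tests, alternatives and the rule for naming genes. The tests were planned with transcription starts and with placement on known bases. Gene ends and the stretch between the outermost genes of an arm took their place. The lists were the bithorax and Antennapedia complexes, architectural and insulator proteins, Polycomb and trithorax group, segmentation, dorsoventral patterning, neural determination and Notch pathway, cell cycle and replication, heat shock proteins, cytoplasmic and mitochondrial ribosomal proteins, replication-dependent histones, and abundant housekeeping transcripts. Symbols matched for 450 members, 1 of them through an older symbol. For the bithorax and Antennapedia complexes the gene span and 1 kb around it counted. Benjamini-Hochberg adjustment was made over the lists of each protein. The bithorax region spans Ubx to Abd-B plus 30 kb on each side.

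The rule for naming genes took the 12 peaks with the highest −log10 q in each list, all shared peaks if at most 15, every peak of the bithorax and Antennapedia complexes, up to 4 members of each gene list by fold enrichment, and the genes of ZAF1 and dCTCF. A gene that this rule names among the ribosomal proteins is not reported here. The p-values measure the placement of peaks, which are not biological replicates, and neighbouring genes can share a peak. Intervals cover counting of peaks only. Alternatives were other windows (250 bp, 500 bp, 2 kb), other definitions of overlap, only the stronger part of each list (45 ZAF1 and 355 dCTCF peaks), peak midpoints, all annotated genes, and lists without shared peaks. The use of 1 replicate call for ranking and of the span of the dCTCF peaks for placement was chosen after seeing the data. Leaving out a ZAF1 library was not possible, as only 1 merged ZAF1 list was available. Peaks on the mitochondrial genome and on an unplaced scaffold stayed out of the tests.

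The tests were tried on simulated peaks before use. In 200 simulations of 91 peaks without planted overlap the overlap test called 1.5% and the gene-end test 3%, and both called 100% with 8 overlaps planted or with the observed distances to random gene ends. The gene list test called 4.5% of random lists of 30 genes and 100% of lists with 8 bound members planted. Peaks without a planted signal were placed by the same rule as in the tests, so their low rates check the computation only. Simulated bound genes were drawn independently and were more numerous than genes near ZAF1 peaks. The rates of the gene list test therefore do not carry over to the ZAF1 list. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.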

Results

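Chromatin from whole Oregon-R embryos of Drosophila melanogaster, collected over 12 h after egg laying, was immunoprecipitated with rat antibodies against ZAF1 (raised to amino acids 105 to 225) or dCTCF (amino acids 612 to 818). ZAF1 and dCTCF are DNA-binding proteins of the architectural or insulator class, and dCTCF is the fly homologue of the vertebrate insulator protein CTCF. There were 2 ZAF1 libraries, 1 dCTCF library and 1 library made with preimmune rat IgG, which served as the control for both peak lists. The values examined were the authors' peak calls, so read depth per library was unknown and no measure of binding was compared between the lists by height. The ZAF1 list, named as merged, held 92 peaks, 91 of them on the chromosome arms. The dCTCF list held 712 peaks, 710 of them on the arms. Fold enrichment is the authors' value for each peak, and its size was not compared between the lists.

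ZAF1 occupied a short list of sites, most of them close to the ends of genes. Its median fold enrichment was 10.9 (range 1.92 to 21.2), with 49 of 92 peaks at 10-fold or more and 27 below 5-fold. The strongest ZAF1 peak lay on arm 3L at 5812957 to 5813822 (dm6), in the gap of 244 bp between vn, which encodes a neuregulin-like ligand of the EGF receptor, and mad2, a spindle checkpoint gene, with a fold enrichment of 21.2. The next by q-value lay near Moca-cyp (19.6), a cyclophilin-family gene, near CG5445 (20.6) and between CG4627 and the aquaporin gene AQP (20.2). A peak inside CtsL1, a cathepsin L gene, reached 19.8, and a peak between CG8611 and CG12994 reached 20.1. The remaining 6 of the 12 leading peaks lay where CG17724, the zinc-finger gene seq and the histone demethylase gene Kdm4B overlap (18.4), between Cpes and the TDP-43 homologue TBPH (17.7), where CG17931 and CG42446 overlap (19.8), beside the homeobox gene C15 (18.3), between the mitotic cyclin gene CycB and stl (18.9), and between CG18661 and alien (18.9), which encodes a COP9 signalosome subunit. Each ZAF1 peak also carried the −log10 p of 2 replicate calls, and across the 92 peaks these gave a Pearson r of 0.986 and a Spearman's rho of 0.976. Peaks are not independent replicates, and the list held only peaks that had already matched between the calls. The median difference between the calls was 6.65% of their mean in the 46 stronger peaks and 18.1% in the 46 weaker ones.

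**Figure D1:**
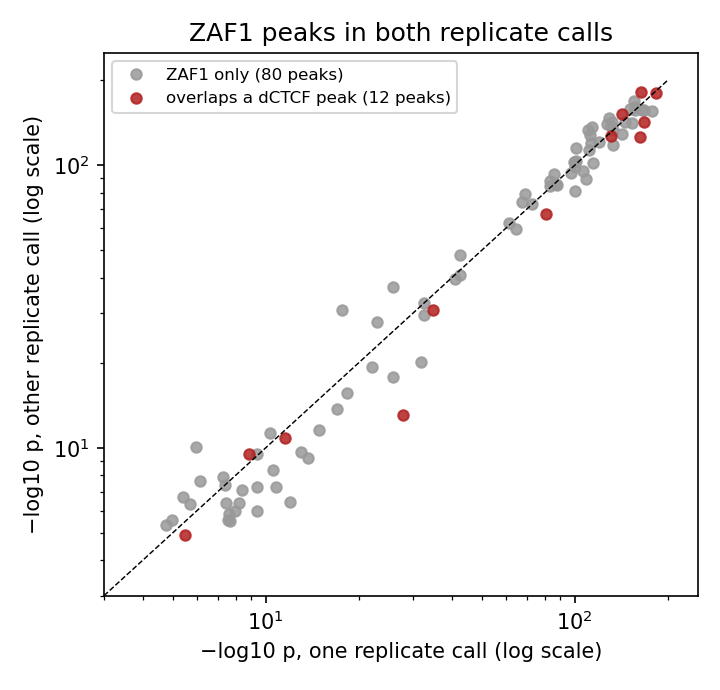
The −log10 p of each ZAF1 peak in one replicate call (horizontal) against the other (vertical), both on log scales, with a dashed line where they are equal; points in red overlap a dCTCF peak. The 92 peaks follow the line (Pearson r 0.986), and the 12 that overlap a dCTCF peak, the mitochondrial one included, are spread along it.

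The dCTCF list was longer, and its strongest peaks lay both inside genes and between them. Its median fold enrichment was 14.1 (range 2.79 to 70.5), with 453 of 712 peaks at 10-fold or more. The strongest peak, on X at 1952888 to 1953366, was inside the nuclear receptor gene Hr4 (70.5). Next came peaks between sgll and CG2993 (68.3), inside the homeobox gene otp (68.5), beside the RhoGAP gene cv-c (65.3), beside dco (66.2), which encodes the clock kinase casein kinase 1, and inside klar (68.0). The other leading peaks lay near Jhbp1 (67.8) and the innexin gene shakB (62.5), inside the muscle regulator Mef2 (63.4), inside the dioxygenase gene Tet (63.4), inside the ecdysone receptor gene EcR (64.2) and near the SOX-family gene Sox21b (55.4). dCTCF had 1 library, so its peaks have no replicate check.

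Whether the proteins shared sites was asked by overlapping the lists. ZAF1 and dCTCF peaks coincided at 11 places on the arms, most of them close to gene ends. These were the gaps beside vn and mad2, Moca-cyp, CG18661 and alien, CycB and stl, and CHES-1-like, a forkhead gene. The others were at CG8569 and CG33632, at the deadenylase gene Pop2, beside the DNA repair gene Fancm, inside the RNA-binding protein gene Rbfox1, at the ribosomal protein gene RpS21, and between tara and bor. The 11 shared peaks were 12.1% of the 91 ZAF1 peaks (95% Wilson interval 6.89 to 20.4), and random placement of the ZAF1 peaks within their arms gave a mean of 0.461 overlaps (95% range 0 to 2; permutation p = 0.0002, two-sided, the smallest that 10000 placements can give). When each peak kept its distance from a gene end, placements gave 1.28 overlaps (95% range 0 to 4; permutation p = 0.0002). Summits of shared peaks lay a median of 34 bp apart (range 5 to 458 bp), and 9 of 11 lay within 1 kb of a gene end. Only 1 of the 91 strongest dCTCF peaks overlapped a ZAF1 peak, and this count did not pass the threshold (placed mean 0.068, permutation p = 0.132). That site, between tara and bor, is one of the 2 ZAF1 peaks with a q above 0.05, and its summits lay 458 bp apart.

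The sites in both lists ranged over the strengths of each list. In the ZAF1 list the vn and mad2 site had a fold enrichment of 21.2, the CycB site 18.9, the Pop2 site 12.0 and the RpS21 site 4.43. In the dCTCF list the fold enrichment was 38.1 beside CHES-1-like, 35.8 between tara and bor, 27.8 at CycB, 26.3 at RpS21 and 4.36 between CG18661 and alien. The median fold enrichment of shared and other peaks was 16.4 and 10.5 in the ZAF1 list (difference 5.91, permutation p = 0.0971) and 23.7 and 14.0 in the dCTCF list (difference 9.76, permutation p = 0.0626), and neither difference passed the threshold. For the 80 ZAF1 peaks without an overlap, no excess of dCTCF summits nearby was detected against placements that were likewise required to overlap no dCTCF peak. None had a summit within 2 kb (placed mean 1.28, 95% range 0 to 4, permutation p = 0.557), and 7 had one within 10 kb (placed mean 7.49, 95% range 3 to 13, permutation p = 1).

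Both proteins lay near gene ends, and ZAF1 did so more often. Of the 91 ZAF1 summits, 72 (79.1%, 95% Wilson interval 69.7 to 86.2) lay within 1 kb of an end of a protein-coding gene, against 24.9% of randomly placed summits. Of the 710 dCTCF summits, 392 (55.2%, interval 51.5 to 58.8) did, against 24.7% of placed ones, and both excesses had a permutation p of 0.0002. The shares differed by 23.9 percentage points (odds ratio 3.07, two-sided Fisher's exact p = 8.69e-06). The median distance to a gene end was 210 bp for ZAF1 and 704.5 bp for dCTCF. The gene table used here gives no strand, so either end of a gene stood in for the transcription start, and starts and 3′ ends were not separated.

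**Figure D2:**
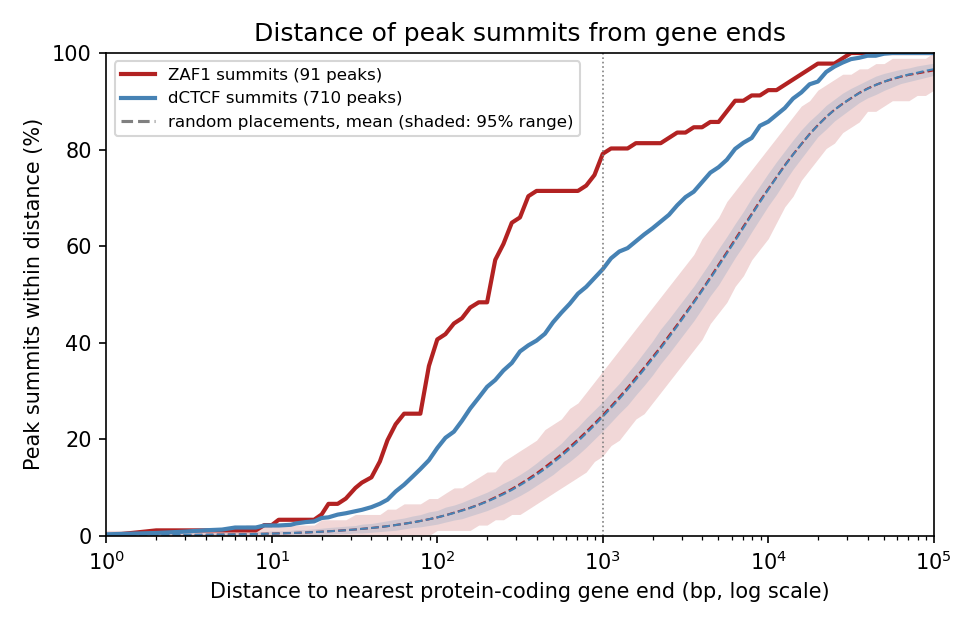
Share of peak summits (vertical, percent) within a given distance of the nearest protein-coding gene end (horizontal, bp, log scale) for the 91 ZAF1 and 710 dCTCF peaks on the arms; dashed lines are means of random placements and shading their 95% range. At the dotted line, 1 kb, the shares are 79.1% for ZAF1 and 55.2% for dCTCF.

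Narrow gaps between neighbouring genes held many of these sites. Gaps of at most 1 kb between protein-coding genes, such as those at vn and mad2, TBPH and Cpes, or CycB and stl, held 36 of the 91 ZAF1 summits (39.6%) against 1.66% of placed ones. They held 148 of the 710 dCTCF summits (20.8%) against 1.63% of placed ones (permutation p = 0.0002 for each list). ZAF1 was in such gaps more often than dCTCF (odds ratio 2.49, Fisher's exact p = 0.00017). A summit in such a gap lies within about 500 bp of a gene end, as 65 of 91 ZAF1 and 313 of 710 dCTCF summits did. The comparison is therefore not separate from the difference in gene-end shares. Gaps were not set against gene-end-matched placements. Sites inside a gene and over 1 kb from any gene end made up 15.4% of ZAF1 and 27.9% of dCTCF summits (odds ratio 0.47, Fisher's exact p = 0.0112), against 49.7% and 49.6% of placed summits. Gaps over 10 kb held fewer summits than placed, with 10 of 91 for ZAF1 (23.5% placed, permutation p = 0.0042) and 142 of 710 for dCTCF (23.8% placed, permutation p = 0.0168), and the difference between the lists in this class was not tested.

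dCTCF peaks were dense in the bithorax complex, the homeotic gene cluster of Ubx, abd-A and Abd-B, and the ZAF1 list had none there. Between 16626623 and 17002236 on 3R there were 11 dCTCF peaks, against a placed mean of 1.80 (permutation p = 0.0002), and 0 ZAF1 peaks (placed mean 0.302, permutation p = 1). No dCTCF peak lay inside Ubx or abd-A, and 3 lay inside Abd-B. Starting from the Ubx side, summits at 16748743 (fold enrichment 49.4, 14317 bp from Ubx), 16782606 (5.47) and 16798886 (51.0) lay between Ubx and abd-A. Those at 16834853 (34.7), 16857216 (37.2), 16869362 (28.5) and 16882769 (27.7) lay inside MSAmiP, between abd-A and Abd-B. The summit at 16919248 (52.1) was 7964 bp outside Abd-B, and those at 16934924 (10.2), 16957962 (41.3) and 16969698 (30.0) were within it. Because the region would hold 0.302 ZAF1 peaks by placement, the absence of ZAF1 is not distinguishable from chance.

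**Figure D3:**
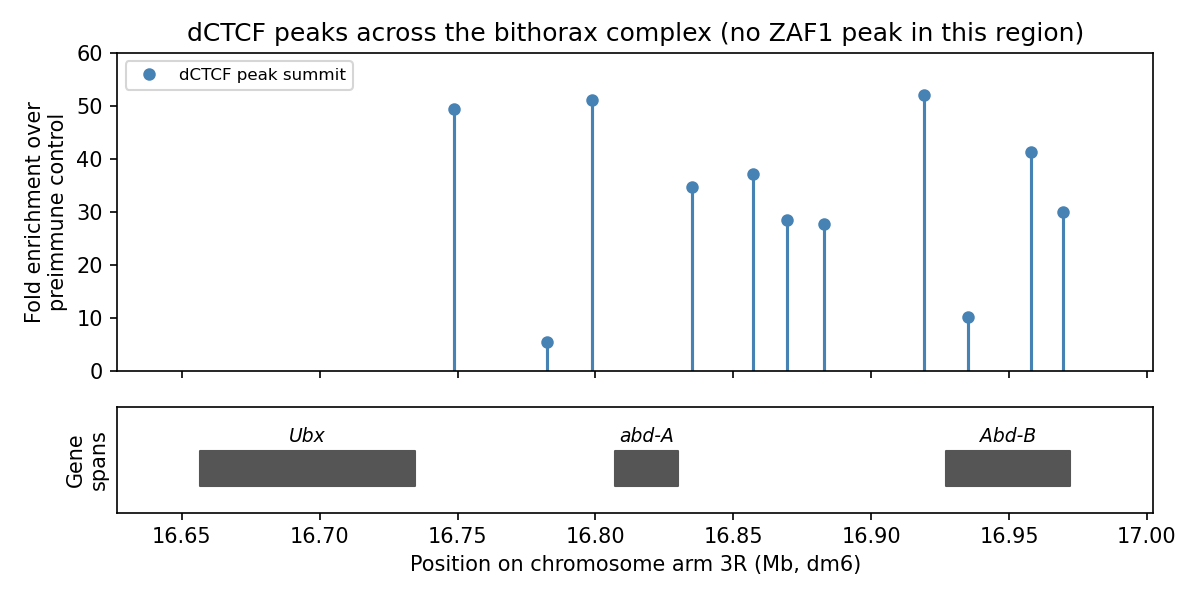
Map of the bithorax complex on 3R (horizontal, Mb) with the fold enrichment of each dCTCF peak over the control (vertical, 1 point per peak summit) and the spans of Ubx, abd-A and Abd-B below. The 11 peaks lie between Ubx and the far end of Abd-B, the highest at 52.1 just outside Abd-B.

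The Antennapedia complex, the homeotic cluster of the head and anterior thorax, held 7 dCTCF peaks between 6661427 and 6999228 on 3R (placed mean 1.63, permutation p = 0.0036) and 0 ZAF1 peaks. The highest, with a fold enrichment of 57.0, lay 222 bp from bcd, the gene of the anterior morphogen Bicoid. The peaks inside Antp had fold enrichments of 29.5, 17.9 and 23.9. The remaining peaks lay near the cuticle gene Edg84A (11.1) and between the homeotic gene Scr and the pair-rule gene ftz or beyond ftz (8.72 and 14.4). The test of the count of 7 was not among those planned in advance. Its region had no 30 kb flanks, unlike the bithorax region.

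Of 13 gene lists fixed in advance, 1 passed the test as over-represented at ZAF1 peaks, the cytoplasmic ribosomal proteins. A member counted as bound with a summit within 1 kb of either end. ZAF1 lay at RpS21 (fold enrichment 4.43), RpS28b (4.23), RpL34b (4.02), RpL23A (3.65) and RpL30 (2.99), which is 5 of 92 members (5.43%) against 0.898% of all 13922 protein-coding genes (odds ratio 6.57, Fisher's exact adjusted p = 0.0185 over 13 lists). All 5 peaks belonged to the weaker part of the list, and the 45 strongest ZAF1 peaks bound 0 of the 92, where 0.489 would be bound by chance. For other lists ZAF1 had 1 bound member each, ZIPIC (4.16) among 23 architectural and insulator proteins, CycB (18.9) among 29 cell cycle genes and mRpL30 (8.34) among 73 mitochondrial ribosomal proteins, and none of these lists passed (lowest Fisher's exact adjusted p = 0.998). It bound 0 of 3 bithorax, 10 Antennapedia, 25 Polycomb and trithorax, 25 segmentation, 18 dorsoventral, 17 neural and Notch, 13 heat shock, 111 histone and 11 abundant housekeeping genes.

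For dCTCF no list passed adjustment. Cytoplasmic ribosomal proteins had 10 of 92 members bound (10.9% against 4.45% of all genes, odds ratio 2.65, Fisher's exact p = 0.00762, adjusted p = 0.0656), among them RpS28a (35.5), RpS21 (26.3) and RpLP1 (19.2), and with a window of 500 bp the list passed (9 members, adjusted p = 0.0415). Replication-dependent histone genes had 0 of 111 bound (Fisher's exact p = 0.0101, adjusted p = 0.0656), and as tandem near-identical copies they are uncertain in any alignment. The test counts the copies as independent genes, which tandem copies are not, so its p-value overstates the evidence. Cell cycle genes had 3 of 29, E2f1 (57.8), CycB (27.8) and the Cdc25 phosphatase gene stg (19.3), and neural and Notch genes 2 of 17, the receptor gene N (46.1) and its antagonist numb (4.35). Among the remaining lists, dCTCF bound Abd-B of the bithorax list, bcd and Antp of the Antennapedia list, bcd of the segmentation list, CTCF (25.9) of the architectural proteins, Sfmbt (10.4) of the Polycomb group, and mRpS18C (16.04) and mRpL47 (5.33) of the mitochondrial ribosomal proteins. It bound 0 of 18 dorsoventral, 13 heat shock and 11 abundant housekeeping genes.

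At the genes encoding the proteins themselves, a dCTCF peak lay inside CTCF, 191 bp from a gene end on 3L at 7356301 to 7356807, with a fold enrichment of 25.9. The ZAF1 list had no peak near Zaf1, the closest summit lying 1336067 bp away on 3R, and the closest dCTCF summit to Zaf1 was 8119 bp away. Peaks followed arm length in both lists, at 0.686 per Mb for ZAF1 and 5.35 per Mb for dCTCF (permutation p = 0.749 and 0.29). The X held 17 ZAF1 and 139 dCTCF peaks, with no difference between the lists (odds ratio 0.944, Fisher's exact p = 1).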

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

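The correlation of fold enrichments at shared sites, the comparison of gene-end shares with only the strongest dCTCF peaks, the split of ribosomal protein peaks by strength, and the counts of genes near both lists were chosen after the results were seen.

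The share of peaks near gene ends differed between the proteins by 23.9 percentage points (ZAF1 79.1%, dCTCF 55.2%, Fisher's exact p = 8.69e-06). A longer tail of weak peaks in the dCTCF list is argued against only as the whole explanation. Among the 91 strongest dCTCF peaks the share was 52.7%, below that of all 91 ZAF1 peaks (Fisher's exact p = 0.000287). In the stronger part of each list it was 60.6% for dCTCF and 88.9% for ZAF1 (Fisher's exact p = 0.000111). The dCTCF share did not rise steadily with strength and was higher in its stronger part than in the whole list. The difference between the lists was 28.3 percentage points in the stronger parts and 26.4 with the 91 strongest dCTCF peaks. Neither was below the 23.9 of the whole lists, so a part played by weak peaks was not shown, and it is not excluded. The ZAF1 list was filtered on agreement between replicate calls and the dCTCF list was not, the antibodies differ, and depth is unknown, so a technical part stays open. That ZAF1 may be more often a protein of short intergenic gaps is a hypothesis from the same data, with no test separate from the antibody or from nearness to gene ends.

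The overlap of 11 peaks lies above what distance from gene ends alone gave, since gene-end-matched placements reached 4 at the upper end of their 95% range and 7 at most. These placements did not match gene starts against 3′ ends, or narrow gaps between genes. A common preference for either is therefore not excluded. Sites enriched with any antibody stay open: at the 11 shared sites the fold enrichments of the lists gave a Spearman's rho of -0.2 (permutation p = 0.563), which decides nothing. Part of the excess may come from the preimmune library that both lists share, which peak lists do not allow to be split. By genes, 19 lay within 1 kb of summits in both lists against 5.56 for independent lists of 125 and 619 genes, which mostly restates the same sites, since neighbouring genes share a peak. Open chromatin at these sites was not tested, and no biological explanation was tested.

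Ribosomal protein genes appeared among the weaker ZAF1 peaks, 5 of 5 in the weaker part of the list against 41 of 86 other peaks (Fisher's exact p = 0.0557). A non-specific signal at strongly transcribed genes predicts that ribosomal protein genes as a group are over-represented in the dCTCF list too. There the odds ratio of the whole list was 2.65 (Fisher's exact p = 0.00762, adjusted p = 0.0656). This explanation is therefore not excluded, and the test does not set it above other explanations. Too few genes were bound to go further: 1 gene, RpS21, was near both lists where independent lists give 0.543 (Fisher's exact p = 0.445), and 0 of 11 abundant housekeeping genes were bound in either list, and neither count decides for or against it. The 10 dCTCF peaks at these genes had 5 in the weaker part of that list. Their median fold enrichment was 15.7 against 14.1 for all dCTCF peaks, while the 5 ZAF1 peaks had 4.02 against 11.1 for all ZAF1 peaks on the arms. Copies and pseudogenes of ribosomal protein genes were not separated.

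On the mitochondrial genome, outside the main comparisons, the ZAF1 list had a peak at 1 to 1595 with a fold enrichment of 1.92 over the preimmune control. The dCTCF list had a peak at 1328 to 1557 with a fold enrichment of 3.88, over tRNA genes and the start of COX1. A dCTCF peak on an unplaced scaffold of X, at 2094 to 2400, had a fold enrichment of 5.20.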

How the results depend on the processing

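Ranking by 1 replicate call, placement within the span of the dCTCF peaks, gap and host-gene lengths, whole-gene windows for lists, and placements kept clear of dCTCF peaks were chosen after the data were seen. Of 165 alternatives, 39 with a test for the main results kept direction and side of the threshold, and for the overlap also a count within 1.5 times of 11. Overlap alternatives that kept direction and threshold outside that limit are not among the 39 and are given below. Sharing defined by summits within 500 bp gave the same medians of shared and other peaks as the main setting, so it adds no check. For other results, 58 with a test kept the side of the threshold, and some gene lists among them changed direction. For example, the odds ratio of dCTCF segmentation genes went from 0.895 to 1.23 with a window of 500 bp. A further 7 gave counts without a test that stayed within 1.5 times. Another 49 were gene lists with 0 bound members throughout, most of them with too few expected to read a direction. The dCTCF histones among them would hold 4.94 members by chance in the main setting if the copies were independent genes. They are tandem copies, so their 0 does not show a shortfall. The gene-end shares and the difference between the lists held under all alternatives run. With both lists treated alike the difference ranged from 17.5 to 28.3 percentage points. It was 33.7 and 35.9 points where the 45 strongest ZAF1 peaks by each replicate call were set against all 710 dCTCF peaks. The bithorax count was 11 without flanks and 9 among the stronger dCTCF peaks. The overlap of 11 peaks became 7 with summits within 100 bp and 4 in the stronger part of each list, and 7 and 6 for the 45 strongest ZAF1 peaks by the first and the second replicate call, each with permutation p = 0.0002. With only as many dCTCF peaks as ZAF1 peaks it was 1 and no longer passed (permutation p = 0.132), where fewer peaks were tested. Among the stronger ZAF1 peaks 0 gene lists passed, with 0 ribosomal protein genes bound where 0.489 would be by chance, too few to show a direction. With a window of 500 bp 1 dCTCF list passed, the ribosomal proteins (Fisher's exact adjusted p = 0.0415). Histones passed as depleted for dCTCF with a window of 2 kb (Fisher's exact adjusted p = 0.0254) and with whole genes (adjusted p = 0.0386). Both tests count tandem copies as independent genes, so a depletion is not established. ZAF1 peaks inside genes lay in shorter genes than placed (13.6 kb against 27.9 kb, permutation p = 0.016), and among the stronger peaks, with 13 peaks inside genes in place of 33, the difference did not pass (21.8 kb against 28.3 kb, permutation p = 0.599), while for dCTCF the genes were not shorter (31.3 kb against 26.9 kb, permutation p = 0.0979, and 33.1 kb against 27.2 kb among the stronger peaks, permutation p = 0.148). These are medians of the length of the longest protein-coding gene over a summit, against uniform placements only. Of the 33 ZAF1 summits inside genes, 14 lay over 1 kb from any gene end. The shorter genes of ZAF1 are therefore not told apart from its nearness to gene ends. The cause was not tested for any of the changes above. The CTCF core, leading sequence words, matching on base composition, divergent starts and exon classes were not run for lack of sequence and strand. No paired analysis was possible, as dCTCF had 1 library and only peak lists were available. Depth is unknown, so its effect on the lengths of the lists is open.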

Other observations

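All tests here were chosen after the lists were seen, and genes named here were picked after their values were seen.

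Some ZAF1 peaks not named so far lay at well-studied genes, which form no tested group. A peak with a fold enrichment of 16.2 lay between p53, the tumour suppressor homologue, and Ctns, and a peak of 13.7 between the energy sensor kinase gene AMPKalpha and ssx. A peak of 14.1 was inside Jra, the fly Jun gene, and a peak of 5.58 lay in the gap of 710 bp between the kinase genes lic and hep, of which hep acts upstream of Jun kinase. Further peaks lay between Tango5 and the autophagy gene Atg8a (18.98), beside the chromatin remodelling ATPase gene Iswi (11.2), between Spn28F and the receptor gene Pvr (7.47), and inside Mad (5.68), the transducer of Dpp signals.

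The most peaks in any stretch of 300 kb for dCTCF was the 11 of the bithorax complex, followed by 8 on 3L from 10225418 on, of which the last, a shared site, lies inside Rbfox1. Of 710 dCTCF peaks, 120 had another within 10 kb against 71.7 in uniform placements (permutation p = 0.002, the smallest that 1000 placements give). Gene-end-matched placements gave 139 (permutation p = 0.226). With runs of summits within 2 kb of each other counted once, in the data and the placements alike, 80 of 689 (11.6%) had a neighbour within 10 kb, against 8.18% in uniform placements (permutation p = 0.018) and 15.0% in gene-end-matched ones (permutation p = 0.0699). Within 10 kb and within 20 kb, fewer dCTCF peaks had a neighbour than in gene-end-matched placements, and the difference passed the threshold only within 20 kb. There, 189 peaks had a neighbour against 224 in matched placements (permutation p = 0.03). With runs counted once, the shares within 20 kb were 21.8% against 27.9% (permutation p = 0.008). For ZAF1 the count was 4 of 91 against 1.26 in uniform placements (permutation p = 0.27).

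For 6 classes of non-coding RNA genes, both lists and both kinds of placement, 24 tests were made and adjusted together. In these, 23 dCTCF summits lay within 1 kb of an antisense RNA gene against 8.28 in uniform placements (permutation p = 0.002, adjusted p = 0.048), but gene-end-matched placements gave 22.0 (permutation p = 0.889). Long non-coding RNA genes had 42 such summits against 26.4 in gene-end-matched placements (permutation p = 0.004, adjusted p = 0.048) and 27.5 in uniform ones (adjusted p = 0.0959), a result at the edge of the threshold.

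The hypothesis that stronger dCTCF peaks lie farther from gene ends was prompted by the leading peaks inside Hr4, Mef2, Tet and EcR. Across the 710 peaks no rising trend was found, with a Spearman's rho between fold enrichment and distance of -0.0571 (permutation p = 0.131). Strength and distance were still not unrelated. With the peaks in 4 groups of nearly equal size by strength, the share near a gene end from the weakest group up was 47.2%, 52.0%, 67.8% and 53.9% (chi-square 16.8, permutation p = 0.0007), highest in the group below the strongest. For ZAF1 the shares were 56.5%, 82.6%, 95.5% and 82.6%, whose differences were not tested, and Spearman's rho between fold enrichment and distance was -0.196 (permutation p = 0.0601).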
